A study of Homo sapiens with 4 samples.

How the data were processed

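Total RNA from Ramos cells, parental or knocked out for ST14, was enriched for polyadenylated RNA, made into libraries from 1 µg of RNA and sequenced with paired reads of 150 bp, per the labels' protocols, which also describe the libraries as strand-specific. Per the submitters' processing notes and the series design text, read quality was checked with FastQC, reads were trimmed of adapter sequence and of bases with low quality, and transcripts were quantified against the GRCh38 transcriptome of Ensembl release 114 with Salmon 1.10.0 and kallisto 0.46.1. The authors deposited 1 table of whole-number counts per Ensembl gene for the 4 libraries, with no normalization. No source used here states how the quantified transcripts became whole-number counts, which of the named tools gave them or whether strand was used in the counting. The gene IDs of the table stop before 10519 genes of GENCODE version 44 that carry later IDs, so the annotation behind the counts is not settled, and genes annotated only recently have no value. Where strand was not used, reads of a gene and of a partner on the opposite strand cannot be told apart, and 9 of the 24 named genes overlap another tested gene.

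Each column was assigned to its sample by the library name in the labels. The table held 57905 gene IDs, and 89.8% of them matched GENCODE version 44 by ID, from which symbols, gene types, strands and GRCh38 positions were taken. Unmatched IDs held between 0.686% and 0.777% of the counts of a library and stayed in the fit under their ID. Library totals ran from 16149938 to 17492901 counts. The 10 most abundant genes took between 6.29% and 6.84% of a library and mitochondrial genes between 3.33% and 3.48%. No pair of libraries agreed within sampling noise (chi-square per degree of freedom between 18.6 and 42.7), so no library was entered again under another name. That they are separate samples rests on the labels.

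Genes with at least 1 CPM in at least 1 library were tested (14058 genes). Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood method with robust estimation, with genotype as the only term. This left 2 residual degrees of freedom, all from the 3 clones. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. An exact permutation of the 4 libraries cannot give a p below 0.25. Standard errors of log2 folds are the size of the fold divided by the square root of the test's F. CPM values were computed from TMM-scaled library sizes, and log2 folds per clone from log2 CPM with a prior count of 2. The filter on low counts and the sums of cell-type markers used library totals without TMM factors. The count by size used log2(CPM + 1) among genes with a mean of at least 5 CPM. Intervals of ratios for genes with few counts are exact, at 95%. A lower bound on a fold allows 3 counts where none was seen and takes the other count as it stands. Both cover counting error only.

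Gene lists for 37 pathways and cell types and the ribosomal proteins were fixed before the data were examined, as were the main tests, the rule for named genes and most of the alternative settings. Lists with at least 5 measured members (34) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. Alternatives were an estimated correlation and fry. With an estimated correlation camera refers its statistic to the 2 residual degrees of freedom, which leaves it little power in this design. The erythroid, myeloid, NK-cell and T-cell lists had fewer measured members and are given as levels. The rule for named genes took ST14 and the matriptase system, then the 12 higher and 12 lower genes past the threshold with a symbol, a mean of at least 5 CPM and the same sign in all 3 clones, ranked by the smallest fold over the clones, and up to 4 members of a list or genes of a clone.

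After the results had been seen, protein-coding genes with a mean of at least 10 CPM (8598 genes) were ordered along each chromosome and a running median of log2 folds over 9 genes was taken. Runs beyond 0.5 in size were compared with the longest run in 1000 shuffled gene orders. The procedures were tested on 5 simulated data sets drawn from the means, library sizes and spread of the real libraries, with 200 of 14058 genes changed in the comparison of knockout with parental. The test recovered 61.6% of the 2-fold and 94.6% of the 4-fold genes, and 33.6 of 191.8 calls on average were false. A list of 30 genes shifted by 0.5 on the log2 scale had an unadjusted camera p under 0.05 in 5 of 5 simulations. Genes were drawn independently of each other and no unshifted list was tested. The simulations therefore do not show how the list test behaves for correlated genes or how often it calls unchanged lists.

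Alternatives covered the filter on low counts, the scaling between libraries, the test (DESeq2 1.42.0 and limma-voom), the pseudocount, the size of the fold, each clone left out in turn, and, chosen after the results had been seen, the removal of genes in chromosomal runs, of GC content and length trends and of genes that do not code for protein.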

Results

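Messenger RNA was measured in Ramos, an established human B-cell line derived from a Burkitt lymphoma, and in Ramos cells from which ST14 had been knocked out. ST14 encodes matriptase, a serine protease anchored in the plasma membrane. The series comprised 1 library of parental cells and 3 libraries of ST14 knockout cells, 1 from each of 3 clones, all collected after 24 h of incubation in medium. The parental library held 16149938 counts, and the libraries of clones 1, 2 and 3 held 16913154, 17492901 and 16955812 counts. Across 10378 genes, which are not independent replicates, Pearson's r of log2 normalised read counts (CPM, counts scaled to library size) lay between 0.960 and 0.965 for the parental library with each clone and between 0.976 and 0.986 for pairs of clones. The parental population had no replicate library, so every test below takes its spread from the 3 clones and assumes that a parental library would vary as they do. Each clone also had a single library, and the p-values measure only the spread between these libraries.

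ST14 mRNA was lower in each of the 3 knockout clones than in the parental library, and it remained present in all of them. Knockout status is taken from the labels throughout, since no DNA or protein value was at hand to check it. The gene (ENSG00000149418) lies on the plus strand of chromosome 11 between positions 130159782 and 130210362 of GRCh38. The parental library held 834 CPM (13138 counts). Clone 1 held 119 CPM, clone 2 held 333 CPM and clone 3 held 138 CPM, which was 14.3%, 40.0% and 16.5% of the parental level, with a mean of 23.6% ± 14.2 (SD, n = 3 clones). The log2 fold was -2.08 with a standard error of 0.74, and it did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.346). Without clone 2 the log2 fold was -2.70, and it passed the threshold there, where the spread rests on clones 1 and 3 alone. The genes around ST14 were also lower in clones 1 and 3. The 22 scanned genes within 5 Mb had a median log2 fold of -0.83 in clone 1, 0.10 in clone 2 and -0.73 in clone 3, and ST14 lay under every one of them in each clone.

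**Figure D1:**
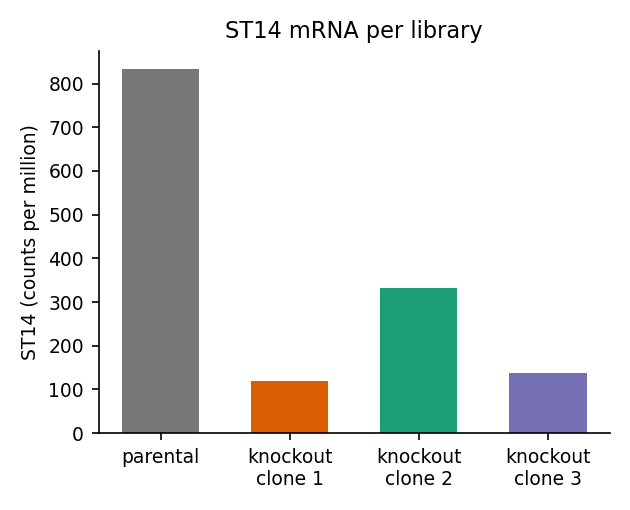
ST14 mRNA in CPM (vertical axis) in the parental library and in each of the 3 knockout clones (1 bar per library, no error bars because each bar is 1 library). The parental bar stands at 834 CPM and the clones at 119, 333 and 138 CPM.

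Inhibitors, substrates and partner proteases of matriptase formed the next group. SPINT2, a Kunitz-type inhibitor of matriptase, was the most abundant after ST14, with 226 CPM in the parental library and 174 ± 26.0 CPM (SD, n = 3) in the clones, a log2 fold of -0.37 (SE 0.18, adjusted p = 0.342). FURIN, a proprotein convertase, had 4.63 CPM in the parental library and 9.34 ± 2.78 CPM in the clones (log2 fold 1.01, SE 0.38, adjusted p = 0.237). PLAU, which encodes urokinase, had 18 counts in the parental library and 1, 2 and 5 counts in the clones (log2 fold -2.82, SE 1.01, adjusted p = 0.218). MET, the receptor for hepatocyte growth factor, had 31 counts in the parental library, 67 in clone 3 and 0 in clones 1 and 2, as did COL3A1, KRT7 and KRT8 in other amounts, described below. None of the 11 measured members passed the test over all genes or adjusted over the list alone.

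The comparison of the knockout clones with the parental library gave the genes that differ between them. A difference between the clones and the parental culture that arose without the loss of ST14 would give the same calls, for single genes and for gene lists, since no clone with ST14 intact was among the libraries. Of 14058 genes tested, 251 passed the threshold, 115 higher and 136 lower in the clones, and each of the 251 had the same sign in all 3 clones. Which direction held more calls depended on the setting, with 187 higher and 153 lower without scaling factors, 311 and 240 in DESeq2, and 49 and 171 in limma-voom. Enzymes and membrane proteins were among the 12 named genes that were higher. CHST6, a sulfotransferase that acts on keratan sulfate, had 0.444 CPM in the parental library and 8.76 ± 1.92 CPM (SD, n = 3) in the clones, a log2 fold of 4.28 (SE 0.48, adjusted p = 0.00827). NDST1, an enzyme that modifies heparan sulfate chains, stood at 1.40 CPM against 16.8 ± 4.12 CPM (log2 fold 3.58, SE 0.41, adjusted p = 0.00981). CBR1, a carbonyl reductase, stood at 0.634 CPM against 8.50 ± 1.13 CPM (log2 fold 3.73, SE 0.41, adjusted p = 0.00763). CECR2, which encodes a bromodomain protein of chromatin remodelling complexes, had 1 count in the parental library and 369 over the 3 clones, a ratio of 113 with a 95% counting interval from 20.1 to 4458. LRP11 (log2 fold 3.56, SE 0.37), MXRA7 (3.03, SE 0.34), REEP2 (3.21, SE 0.41) and BEST1 (3.52, SE 0.59) encode membrane-associated proteins, and BEST1 overlaps FTH1 on the opposite strand. FNIP2, a partner of folliculin, had a log2 fold of 3.22 (SE 0.45), the forkhead factor FOXJ2 of 2.98 (SE 0.37) and the long non-coding RNA LINC00667 of 2.90 (SE 0.27), and LINC00526, which overlaps LINC00667 on the opposite strand, was also called with 3.55. HLA-K, a pseudogene of the HLA class I family, had a log2 fold of 4.52 (SE 0.59) and is uncertain, since reads of its class I relatives can be assigned to it. In limma-voom 9 of the 12 higher genes did not pass, CHST6 (adjusted p = 0.0840), NDST1 (0.0901), CBR1 (0.0542) and CECR2 (0.212) among them, and 0 of the 12 lower genes were lost.

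The 12 named genes that were lower included a B-cell gene, a kinase and an antimicrobial peptide. VPREB3, which is expressed in developing and germinal-centre B cells, fell from 28.5 CPM in the parental library to 7.39 ± 1.35 CPM (SD, n = 3) in the clones, a log2 fold of -1.94 (SE 0.23, adjusted p = 0.00914). FGR, a kinase of the SRC family, fell from 17.6 to 3.17 ± 0.757 CPM (log2 fold -2.47, SE 0.30, adjusted p = 0.0103). CAMP, the cathelicidin antimicrobial peptide, fell from 37.0 to 8.71 ± 2.43 CPM (log2 fold -2.09, SE 0.27, adjusted p = 0.0151). ENG, the TGF-beta co-receptor endoglin, fell from 15.1 to 3.55 ± 0.758 CPM (log2 fold -2.09, SE 0.29, adjusted p = 0.0165). TMEM132A had a log2 fold of -3.16 (SE 0.32), and SLC15A3, which overlaps it on the opposite strand, was also called with -5.72. The microsomal glutathione transferase MGST2 stood at -2.89 (SE 0.33), the carboxylesterase CES3 at -2.72 (SE 0.33), the glycosyltransferase GCNT1 at -1.91 (SE 0.29), LRFN4 at -1.95 (SE 0.30), the calcium sensor NCALD at -1.93 (SE 0.32) and the long non-coding RNA LINC03040 at -2.07 (SE 0.30). The partners of GCNT1, LRFN4, LINC03040 and ENG on the opposite strand were also lower, none of them called, with -2.68 for PRUNE2, -0.89 for PC, -2.68 for SCIRT and -0.70 for an unnamed long non-coding RNA. The partners of other named genes did not follow them as closely, with 0.85 for H3P16 and 0.24 for MAML3, which overlap MGST2, -0.05 for ZBTB14, which overlaps LINC00667, 0.25 for SETD4, which overlaps CBR1, and 0.03 for FTH1, none of them called. GPN2, a GTPase, fell from 77.3 to 16.9 ± 2.43 CPM (log2 fold -2.20, SE 0.17, adjusted p = 0.00249), and it lies within a run of 8 neighbouring genes on the short arm of chromosome 1 that were lower together in all 3 clones (median log2 folds -0.84, -0.84 and -0.99 in clones 1, 2 and 3). The run exceeded the longest shuffled run only in clone 1 (8 genes against 7), and not in clone 2 (8 against 9) or clone 3 (10 against 10). These limits are the highest over 1000 shuffled orders. The median over the orders of the longest run was 1, 1 and 3 genes in clones 1, 2 and 3.

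**Figure D2:**
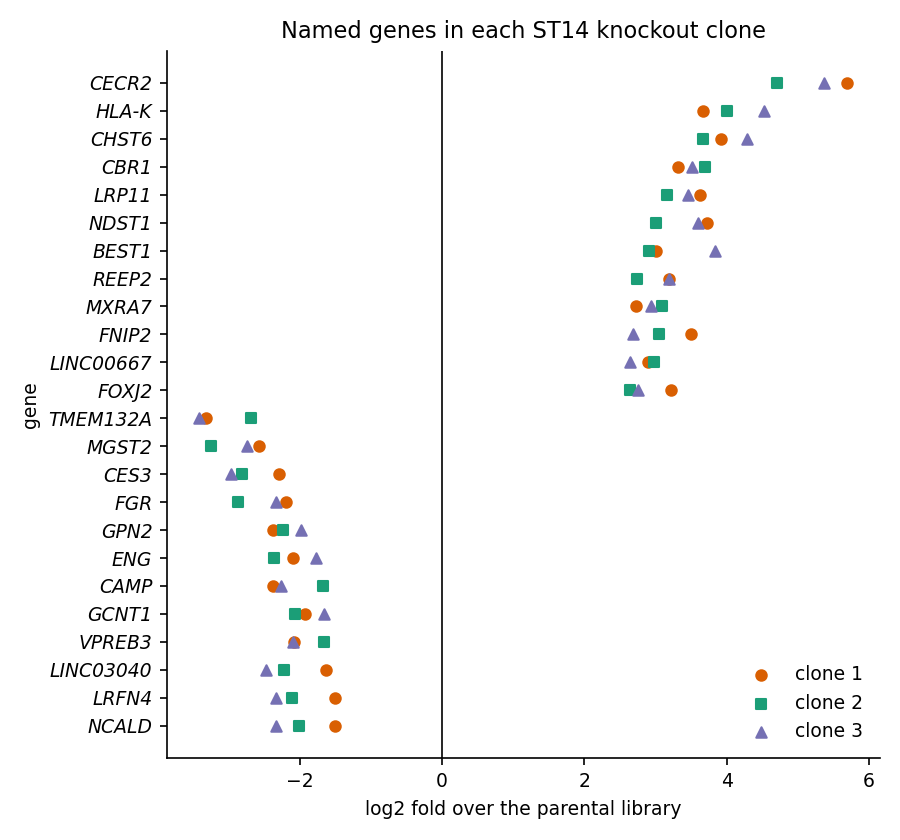
Log2 fold over the parental library (horizontal axis) of the 12 higher and 12 lower named genes (vertical axis) in clone 1 (circles), clone 2 (squares) and clone 3 (triangles), 1 library each. Every gene lies on the same side of 0 in all 3 clones, as the rule for named genes required, from 5.70 for CECR2 in clone 1 to -3.41 for TMEM132A in clone 3.

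A count by size alone, which assumes nothing about the spread of the parental library, gave 166 of 10378 genes at least 2-fold from the parental library in all 3 clones, 110 higher and 56 lower. With clone 1, 2 or 3 in the place of the parental library the same rule gave 12, 38 and 12 genes. Of the 166 genes, 113 were also among the 251. The number of calls depended on which clones gave the spread. Without clone 3 no gene passed in edgeR (1668 at an unadjusted p under 0.05, with 199 calls by DESeq2 and 0 by limma-voom). Without clone 2 the number was 1179. Each of the 251 genes had the same sign in all 3 clones, so leaving out a clone could not change it. In simulated counts of this design 17.5% of the calls were false, so single genes near the threshold carry more error than their adjusted p states.

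Runs of neighbouring genes that were lower together and longer than every shuffled run of their clone held 107 tested genes. Of these, 15 were among the 251 called. All 15 were lower in the clones, which the choice of lowered runs nearly fixes. The clearest run common to the clones was on the long arm of chromosome 13 between 40.73 and 43.89 Mb, where 12 scanned genes had median log2 folds of -0.99, -1.31 and -1.19 in clones 1, 2 and 3. These genes were chosen after their values were seen. The run included ELF1, an ETS-family transcription factor (log2 fold -1.48, SE 0.15, adjusted p = 0.00538), RGCC, a regulator of the cell cycle (-1.39, SE 0.15, adjusted p = 0.00628), and KBTBD6, a substrate adaptor of a ubiquitin ligase (-1.63, SE 0.20, adjusted p = 0.0103). The 3 scanned genes on each side of the run had log2 folds between -0.35 and 0.47. A second stretch of the same arm, from 19.63 Mb, was also lower, in runs of 7, 6 and 5 genes in clones 1, 2 and 3. The median log2 folds of these runs were -0.82, -1.09 and -0.96. None of the runs exceeded the longest run in any of the 1000 shuffled orders of its clone (7, 9 and 10 genes), so their genes are not among the 107. The median over those orders of the longest run was 1, 1 and 3 genes. On the short arm of chromosome 1, HMGN2, a nucleosome-binding protein that shares sequence with its pseudogene HMGN2P5, had a log2 fold of -1.45 (SE 0.13, adjusted p = 0.00372), and ARID1A, a subunit of the SWI/SNF chromatin remodelling complex, had -1.06 (SE 0.15, adjusted p = 0.0147). On the long arm of chromosome 11 a run of 53 genes from 118.40 to 134.27 Mb was lower in clone 3 (median log2 fold -0.76) and a run of 20 genes from 125.88 to 134.27 Mb in clone 1 (median -0.95).

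**Figure D3:**
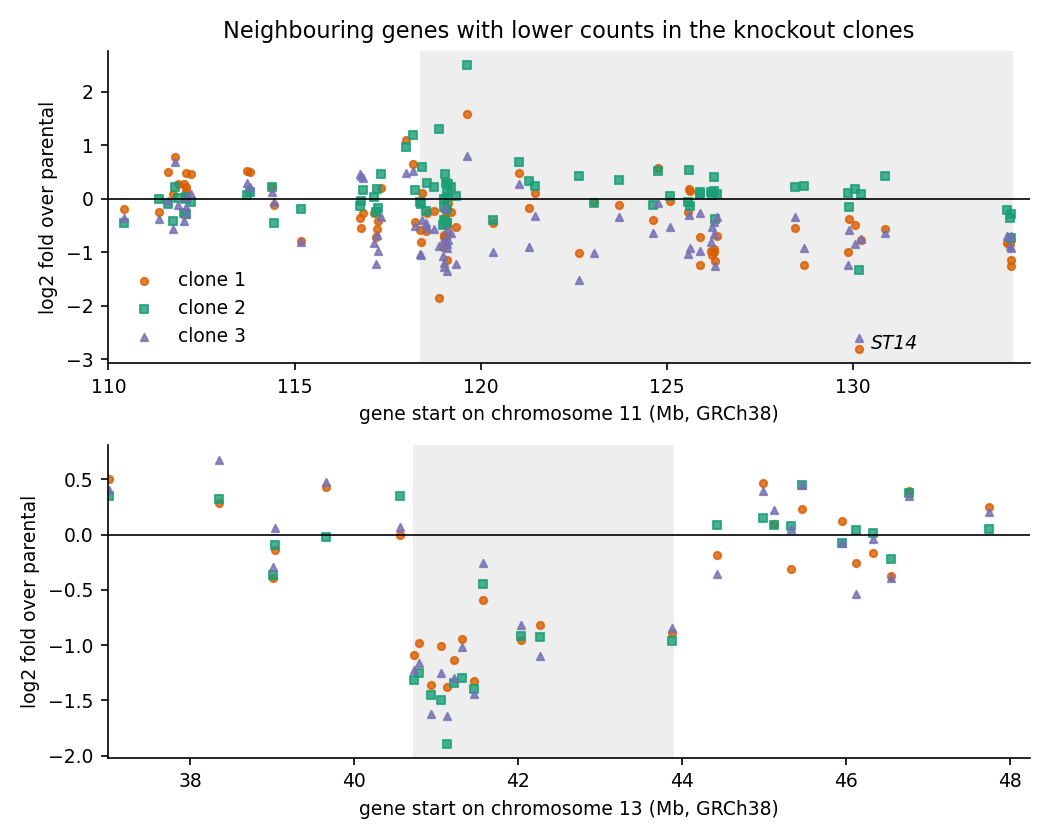
Log2 fold over the parental library (vertical axes) of scanned protein-coding genes by their start in Mb on GRCh38 (horizontal axes) on distal chromosome 11 (top) and part of chromosome 13 (bottom), with 1 point per gene and clone (circles clone 1, squares clone 2, triangles clone 3) and the runs shaded. On chromosome 11 the genes of clones 1 and 3 lie mostly under 0 within the runs, with medians of -0.95 and -0.76, and on chromosome 13 all 3 clones do, with medians of -0.99, -1.31 and -1.19.

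Genes of the interferon response, of antigen presentation by MHC class II and of the NF-kB target list ranked higher in the clones than other genes at a preset inter-gene correlation. These lists did not pass in camera with the correlation estimated from these libraries (adjusted p = 0.850, 0.873 and 0.850). That setting rests on 2 residual degrees of freedom. Its failures, here and below, therefore cannot tell whether inter-gene correlation accounts for the ranks. Of 30 measured interferon response genes, 3 were called higher and 0 lower (12 higher adjusted over the list alone). Of the 30, 21 were positive in all 3 clones, and the median log2 fold was 0.75. The folds of the 3 clones share the parental library, so equal signs here and in the lists below are not independent evidence. SAMD9L rose from 4.57 CPM in the parental library to 27.8 ± 4.14 CPM (SD, n = 3) in the clones (log2 fold 2.60, SE 0.25, adjusted p = 0.00488). MX1, an antiviral GTPase, rose from 16.2 to 61.9 ± 5.30 CPM (1.93, SE 0.17, adjusted p = 0.00372), and IFIT5 from 1.33 to 5.58 ± 0.297 CPM (2.06, SE 0.38, adjusted p = 0.0403). GBP4 had 2 counts in the parental library and 22, 252 and 45 in the clones and did not pass (adjusted p = 0.510). The list had an adjusted p of 3.98e-05 in limma's camera with the preset correlation, and adjusted p = 0.850 with an estimated correlation.

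Of 15 measured MHC class II genes, 0 were called over all genes and 6 were higher adjusted over the list alone, and 11 were positive in all 3 clones, with a median log2 fold of 0.68. HLA-DRA, the alpha chain of HLA-DR, stood at 395 CPM in the parental library and 886 ± 174 CPM (SD, n = 3) in the clones (log2 fold 1.16, SE 0.24, adjusted p = 0.0661). CIITA, the transactivator of these genes, stood at 88.8 against 172 ± 34.8 CPM (0.95, SE 0.23, adjusted p = 0.113), and HLA-DOB at 17.9 against 35.0 ± 4.25 CPM (0.97, SE 0.19, adjusted p = 0.0526). The list had a camera adjusted p of 0.000666 with the preset correlation, and adjusted p = 0.873 with an estimated correlation. Of 26 measured NF-kB targets, 2 were called higher and 0 lower (8 higher adjusted over the list alone). RELB, a subunit of NF-kB, rose from 84.1 to 186 ± 19.7 CPM (1.14, SE 0.17, adjusted p = 0.0213), and BCL3, an atypical IkB protein, from 11.2 to 23.1 ± 0.916 CPM (1.04, SE 0.19, adjusted p = 0.0373). This list had a camera adjusted p of 0.000713, and adjusted p = 0.850 with an estimated correlation.

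Lists of mitochondrial respiration, biosynthesis and proliferation ranked lower in the clones at the preset correlation, by small amounts, and none of them passed with an estimated one. None of the 38 measured genes of oxidative phosphorylation was called, 29 were negative in all 3 clones, and the median log2 fold was -0.26 (camera adjusted p = 3.98e-05, and adjusted p = 0.850 with an estimated correlation). COX5A, a subunit of cytochrome c oxidase, stood at 224 CPM against 142 ± 11.3 CPM (SD, n = 3), with a log2 fold of -0.66 (SE 0.14, adjusted p = 0.0688). The 47 measured MYC targets had a median of -0.21 with 0 calls (camera adjusted p = 0.000220, and adjusted p = 0.850 with an estimated correlation). TERT, the catalytic subunit of telomerase, went against the list with 0.80 (SE 0.16, adjusted p = 0.0520) and was its single gene past the threshold adjusted over the list alone. MYC itself had a log2 fold of -0.27 (SE 0.15, adjusted p = 0.400). The medians were -0.34 for 23 genes of cholesterol synthesis (camera adjusted p = 0.00542), -0.19 for 38 genes of G2/M and mitosis (camera adjusted p = 0.00722) and -0.15 for 38 genes of G1/S and DNA replication (camera adjusted p = 0.0149), again with 0 calls in each. These 3 lists each had adjusted p = 0.954 with an estimated correlation, and the G1/S list did not pass without clone 3 (adjusted p = 0.0934). Of 33 measured genes of hypoxia and glycolysis 1 was called, the lactate transporter SLC16A3, which fell from 16.5 to 0.659 ± 0.441 CPM (-4.63, SE 0.51, adjusted p = 0.0123), and the list had a median of -0.31 (camera adjusted p = 0.0384, and adjusted p = 0.850 with an estimated correlation). It did not pass without clone 2 (adjusted p = 0.0606).

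Immunoglobulin transcripts were lower as a list (9 measured, median log2 fold -0.49, camera adjusted p = 0.00192, and adjusted p = 0.850 with an estimated correlation). IGLL1, a surrogate light chain of precursor B cells, had 52 counts in the parental library and 0 in each clone, which makes it at least 56.8-fold lower when 3 counts are allowed over the 3 clones and the counting error of the 52 is left aside. The exact 95% interval of the ratio, which includes that error, reaches up to 0.0224. It was the only member called. Adjusted over the list alone 6 members were lower and 1 was higher, IGHJ6, with 4 counts in the parental library and 19, 15 and 30 in the clones (log2 fold 2.26, adjusted p = 0.0455 over the list alone). IGHM, the heavy chain of the IgM that Ramos cells carry, stood at 12919 CPM in the parental library and at 8289 ± 42.5 CPM (SD, n = 3) in the clones (log2 fold -0.64, SE 0.17, adjusted p = 0.113). IGHG4 had 22 counts in the parental library and 0, 0 and 1 in the clones (adjusted p = 0.0750). The epithelial list (5 measured, median log2 fold -2.51, camera adjusted p = 0.0104, and adjusted p = 0.850 with an estimated correlation) had 0 calls. JUP, the junctional protein plakoglobin, stood at 49.9 CPM against 8.78 ± 3.69 CPM (-2.51, SE 0.41, adjusted p = 0.0791). The keratins KRT7 and KRT8 had 59 and 46 counts in the parental library, 8 and 18 in clone 3 and 0 in clones 1 and 2. Both belong to a set of transcripts, described below, that may be RNA carried over from other cells or libraries.

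**Figure D4:**
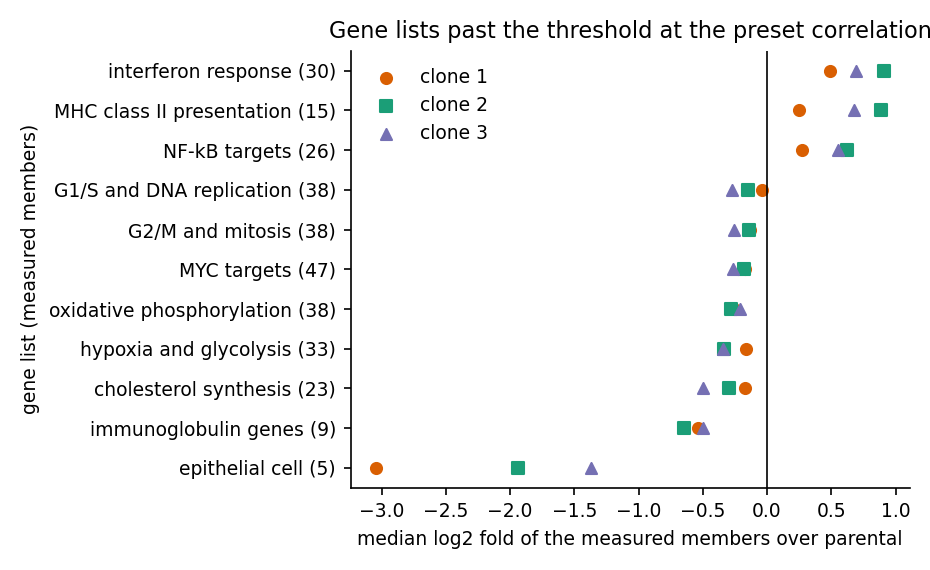
Median log2 fold over the parental library (horizontal axis) of the measured members of the 11 gene lists past the threshold at the preset correlation (vertical axis, members in parentheses) in clone 1 (circles), clone 2 (squares) and clone 3 (triangles). The interferon medians are 0.49, 0.91 and 0.69 and the oxidative phosphorylation medians -0.25, -0.28 and -0.21, and none of the 11 lists passed with an estimated correlation.

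The remaining 23 of the 34 lists tested did not pass in camera, the nearest being Notch signalling (16 measured, median log2 fold -0.23, adjusted p = 0.0802), which passed without clone 1 (adjusted p = 0.0287). Single members of these lists were called. TNFRSF1B, a receptor for tumour necrosis factor, rose from 1.21 to 7.79 ± 1.72 CPM (SD, n = 3; log2 fold 2.68, SE 0.42, adjusted p = 0.0257) among the cytokines and receptors. The Wnt co-receptor LRP5 rose from 3.68 to 19.97 ± 2.03 CPM (2.44, SE 0.25, adjusted p = 0.00538). The intracellular serpin SERPINB8 fell from 5.33 to 0.0965 ± 0.0327 CPM (-5.68, SE 0.60, adjusted p = 0.00629). B-cell identity (28 measured), TGF-beta signalling (17 measured) and the B-cell states outside the germinal centre (19 measured) each held 1 called gene, VPREB3, ENG and IGLL1. The adjusted p in camera was 0.475 for cytokines and receptors, 0.747 for Wnt signalling and for the B-cell states, 0.310 for membrane serine proteases and serpins, and 0.802 for B-cell identity, TGF-beta signalling and the fibroblast and endothelial list (5 measured, 0 calls), which camera ranked higher with all clones and lower without clone 3 (adjusted p = 0.0272). No gene was called in germinal-centre B cell (28 measured, adjusted p = 0.947), B-cell receptor signalling (30, adjusted p = 0.799), plasma-cell differentiation (17, adjusted p = 0.797), MHC class I presentation (17, adjusted p = 0.802) or adhesion and migration receptors (26, adjusted p = 0.869). The same held for extracellular matrix and proteolysis (32, adjusted p = 0.372), which passed as lower without clone 3 (adjusted p = 2.56e-05), for apoptosis regulators (31, adjusted p = 0.639), p53 targets (25, adjusted p = 0.887) and the unfolded protein response (28, adjusted p = 0.236, and 0.0166 without clone 1). It held also for oxidative stress and iron (25, adjusted p = 0.372), HGF-MET, MAPK and immediate early genes (20, adjusted p = 0.802), ribosomal proteins (82, adjusted p = 0.799, and 0.0205 without clone 1), the mitochondrial genome (15, adjusted p = 0.799) and replication-dependent histones (9, adjusted p = 0.214). Some members of the epithelial, fibroblast and matrix lists occurred in the parental library and clone 3 only. As described below, they may be carried-over RNA, so the changes of these lists without clone 3 are uncertain. The sign of the median, the mean and the camera direction differed for 11 of the lists that did not pass, among them the matriptase system (adjusted p = 0.999), B-cell identity, germinal-centre B cell, p53 targets and MHC class I presentation.

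Transcripts that mark other cell types were summed per library. The epithelial markers held 75.0 CPM in the parental library and 24.2, 18.6 and 29.1 CPM in clones 1, 2 and 3. A single gene, JUP, whose levels are given above, made up most of the parental sum. The fibroblast and endothelial markers held 8.05 CPM in the parental library, 3.67 and 3.89 CPM in clones 1 and 2 and 28.6 CPM in clone 3. COL3A1 had 9 counts in the parental library, 180 in clone 3 and 0 in clones 1 and 2. T-cell markers, of which B-cell lines express some, held 283, 292, 442 and 301 CPM. NK-cell markers held 2.11, 2.78, 6.12 and 2.77 CPM, myeloid markers 6.32, 8.57, 15.9 and 9.79 CPM, and erythroid markers 15.6, 21.6, 22.4 and 17.5 CPM, each in the order parental, clone 1, clone 2, clone 3.

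The clones also differed from one another, which was described without a test because each had 1 library. Over 10378 genes the median SD of log2(CPM + 1) across the 3 clones was 0.13. In clone 1, 12 genes were at least 2-fold from all other libraries, in clone 2, 38 genes, and in clone 3, 12 genes. FAR2 stood at 21.6 CPM in clone 1 and at 4.12, 1.63 and 4.23 CPM in the parental library, clone 2 and clone 3. SGK1, a serum- and glucocorticoid-regulated kinase, stood at 19.8 CPM in clone 2 and at 2.47, 2.23 and 2.47 CPM in the parental library, clone 1 and clone 3. PLCB2 had 6 counts in clone 2 and 199, 101 and 147 in the other libraries in the same order, and CA8 had 3 against 166, 147 and 135. DMD, the dystrophin gene, stood at 142 CPM in clone 3 and at 34.2, 31.4 and 34.7 CPM in the parental library, clone 1 and clone 2, and NLRP11 at 23.5 CPM against 3.11, 4.75 and 1.51 CPM.

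The log2 folds of the clones over the parental library were correlated across 10378 genes, which are not independent replicates. Pearson's r was 0.67 for clones 1 and 2, 0.83 for clones 1 and 3 and 0.73 for clones 2 and 3, with a mean of 0.74. All 3 folds share the parental library, and 20 simulations of unchanged libraries with a shared reference gave a mean r of 0.50. The mean covariance was 0.153 against a simulated 0.0594, a difference of 0.0940. With clone 1, 2 or 3 as the reference in place of the parental library the mean r was 0.36, 0.47 and 0.38. The parental library could not be split, so some or all of the excess may come from that single shared library.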

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

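The alternatives without genes in chromosomal runs, without the GC content and length trend and with protein-coding genes only were chosen after the results had been seen. The 251 calls became 1239 with no filter on low counts and 551 in DESeq2's Wald test (311 higher, 240 lower), and with 1 clone left out they ranged from 0 (without clone 3) to 1179 (without clone 2), the spread then resting on a single pair of clones. Without clone 3 the smallest adjusted p was 0.0591, and all 251 genes kept an unadjusted p under 0.05. The cause of the other shifts was not tested. The share of calls that were higher was 45.8% and became 25.2% with quantile normalization in limma-voom (68 higher, 202 lower) and 22.3% in limma-voom without it (49 higher, 171 lower), and without scaling factors it was 55.0% (187 higher, 153 lower). The 24 named genes were chosen for the same sign in all clones, so leaving out a clone could not change it. None changed sign in the other settings. Of their 261 alternative values 43 lost the threshold, 24 of them without clone 3, where each of the 24 genes did. In limma-voom 9 of the 12 higher and 0 of the 12 lower genes lost it, and with quantile normalization 8 and 0. ST14 had log2 folds between -2.70 and -1.82 with 1 clone left out and passed the threshold only without clone 2, where the log2 fold was -2.70. The 166 genes that were at least 2-fold from the parental library became 307 at a mean of at least 1 CPM, 47 at a mean of at least 20 CPM, 79 with a pseudocount of 5, 531 at 1.5-fold and 58 at 3-fold, and between 195 and 273 with 1 clone left out. The 11 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.850 and 0.207), where camera and fry gave 0 and 5 lists at an unadjusted p under 0.05. Camera with an estimated correlation rests on 2 residual degrees of freedom, so its 0 lists cannot decide between correlated genes and low power. Fry asks whether the genes of a list move one way on balance and compares them with no other genes, and its mixed test, for changes in either direction, gave 12 lists. Between 10 and 14 lists passed with 1 clone left out. Without clone 1 the unfolded protein response, ribosomal proteins and Notch signalling were added, without clone 2 hypoxia and glycolysis was lost, and without clone 3 G1/S was lost while extracellular matrix (adjusted p 2.56e-05) and fibroblast and endothelial (0.0272, direction turned to lower) were added; quantile normalization lost 3, both cell cycle lists and hypoxia and glycolysis. At 5 CPM in at least 1 library the epithelial list was too small to test and the serpins were added (0.0267). Without the genes of the chromosomal runs longer than every shuffled run of their clone the counts were 236 calls, 157 genes by size and 11 lists. With protein-coding genes only there were 197 calls. The mean correlation of folds lay between 0.72 and 0.74 under its alternatives. A pseudocount has no place in the test behind the 251 calls, which runs on counts, so it was varied only for the count by size, the correlation of folds and ST14. Salmon and kallisto were not compared, since a single table of counts was used here and its tool is not stated. No paired analysis was possible because there is only 1 parental library. Depth limits genes such as CECR2 and IGLL1, which had 1 count in the parental library or 0 in the clones.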

Other observations

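All tests in this part were chosen after the results had been seen. Some genes were present on one side of the comparison and close to absent on the other, counting at least 15 as present and at most 1 as absent. Present in all 3 clones and absent from the parental library were 13 genes, among them P2RX7, an ATP-gated channel, with 45, 78 and 74 counts in clones 1, 2 and 3 and 0 in the parental library, the scavenger receptor CD36 with 18, 24 and 25 counts against 1, and COL19A1 with 23, 48 and 57 against 0. Present in the parental library and absent from all 3 clones were 35 genes, among them VAT1L with 243 counts, PNMA8A with 200, the troponin TNNI1 with 129, GIMAP6 with 100 and the surrogate light chain IGLL1 with 52, each with 0 or 1 in every clone. Present in clone 2 alone were 2 genes, and in clone 1 or clone 3 alone 0.

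With each library in turn set against the other 3, only 1 of the 4 splits gave as many as 251 calls in edgeR, the one that sets the parental library apart, and the highest of the others gave 0 (224, 476 and 246 genes at an unadjusted p under 0.05 for clones 1, 2 and 3, with the parental library then part of the spread). A design with 4 splits is too small for a share under 0.05.

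ST14 lies in a stretch of chromosome 11 that was lower in clones 1 and 3 and not in clone 2. Over the 22 scanned genes within 5 Mb, the median difference of clones 1 and 3 from clone 2 was -0.745 on the log2 scale, and the lowest of 7633 windows of as many genes on other chromosomes was -0.305, which is consistent with fewer copies of distal 11q in these 2 clones. The run of 20 genes in clone 1 and of 53 in clone 3 exceeded the longest shuffled runs of 7 and 10 genes. The lower level of the neighbours did not account for the whole fall of ST14, whose log2 fold minus its neighbours' median was -1.98, -1.42 and -1.87 in clones 1, 2 and 3 (mean -1.75, SD 0.30), with ST14 under every neighbour in each clone. Whether such a loss arose with the edit or in culture was not tested, and DNA was not analysed here.

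On chromosome 13 between 40.73 and 43.89 Mb, 12 neighbouring genes were lower in all 3 clones by a mean median of -1.16 on the log2 scale. A copy-number difference of the segment between the parental library and the clones is a possible explanation. The runs of 12, 11 and 11 genes exceeded the longest shuffled runs of 7, 9 and 10. The flanking genes stayed between -0.35 and 0.47, and the medians differed little between clones (SD 0.16). All 3 folds share the parental library, so the runs and the similar medians are not independent evidence. A response of these genes to the loss of ST14, with 10 of them called, cannot be told apart from a difference that existed before the edit, since there is 1 parental library and no clone with ST14 intact. A common ancestor cell of the 3 clones, or a change in the parental culture after they were derived, stays open as untested.

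A part of the transcripts that mark adherent cells occurred in the parental library and clone 3 and was close to absent from clones 1 and 2, while others such as COL1A1 (32, 8, 10 and 133 counts in the parental library and clones 1, 2 and 3) did not follow it. Of 75 searched members of the epithelial, fibroblast and matrix lists, 17 had at least 5 counts in these 2 libraries and at most 1 in the others, and any other pair of libraries had 0. Over all genes the number was 109 for this pair and between 14 and 25 for the other pairs, and ZNF503-AS1 (510 and 668 counts), MYOC (143 and 197) and VIM (73 and 58) were among the most abundant. Over the 17 genes the ratio of the 2 libraries had a chi-square per degree of freedom of 15.02 (chi-square 240 on 16 degrees of freedom, p = 4.96e-42 against counting error alone). The ratio ran from 59 against 8 counts for KRT7 to 9 against 180 for COL3A1. A single source of fixed composition would keep 1 ratio, so these values argue against it for the 17 genes. Of 1000 sets of other genes matched on counts, 16 were as high (median 5.55), though such genes may themselves differ between the 2 libraries. RNA carried over from other cells or libraries and expression by a fraction of the Ramos cells cannot be told apart, since the count of 17 is the pattern itself and no other value separates them.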
